A study of Mus musculus with 6 samples.

How the data were processed

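RNA sequencing of mouse oocytes was analysed in 6 libraries, 3 labelled control and 3 labelled AMH. AMH is anti-Müllerian hormone, a member of the TGF-beta family made by granulosa cells of growing follicles. Per the labels' protocols, C57BL/6J mice received 300 ng of recombinant mouse AMH daily into the abdominal cavity from day 21 of age, RNA was amplified with a SMART v4 kit, and messenger RNA was taken with poly-T beads. The labels give an age of 6 to 7 weeks. They do not say how many oocytes of which stage went into each library or whether cumulus cells were removed, so cumulus marker values cannot be set against a known share of such cells. Nor do they say whether the libraries are directional, whether controls were injected, or whether each library is a separate animal, so the p-values measure the spread between these libraries, which may be technical.

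The authors deposited whole-number counts per Ensembl gene, with 1 column per library. HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 and the builds GRCm38 and mm10 are named in the submitters' processing notes. Their roles, filters and strand setting are not given in the sources used here. The count table has 54532 genes, and no row lacks a gene. Of its gene identifiers 99.9% were found in GENCODE M21, and 98.3% of those have identical positions there, so coordinates are those of GRCm38 as in the file. Genes and their antisense partners may share reads where the counting ignored strand. Ribosomal protein genes and Gapdh have many processed pseudogenes, and haemoglobin, histone and Tdpoz genes have near-identical copies, so their counts are uncertain.

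The authors also deposited FPKM values. Each FPKM value equals the count divided by gene length and by 1 effective library size per library. That size matched a median-of-ratios size factor, with a difference of at most 2.9e-10 percent. The effective size was 0.924 to 0.997 of the count total in the controls and 1.05 to 1.18 of it in the AMH libraries.

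Depth was 66392859 to 72109080 counts per library. Pairs of libraries were checked for duplicates with a chi-square statistic over genes with at least 20 counts in the pair. The lowest statistic per degree of freedom was 55.9, far above sampling noise, so each library was counted once. It came from control 3 with AMH 3, a pair across the groups, ahead of 66.0 for controls 1 and 2 and 69.2 for AMH 1 and 2.

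The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust) with TMM scaling, the default filterByExpr filter, a design of group alone and Benjamini-Hochberg adjustment at 0.05 over 18868 genes. Values per gene are CPM on the TMM-scaled library size, given as mean ± SD over 3 libraries. Fold changes are AMH over control, with standard errors from the F statistic. A second count required an absolute log2 fold change of at least 1. FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in genes above 1 FPKM in at least 3 libraries.

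Before the data were examined, 31 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Members past the threshold are counted over all genes tested and adjusted over the list alone. Summed CPM of 7 marker lists and 12 library measures were compared by two-sided exact permutation tests, which with 3 against 3 libraries cannot go below 0.1.

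The rule for named genes took protein-coding genes past the threshold with at least 5 CPM and no overlap between groups. If fewer than 5 passed, it took instead the 10 genes of smallest unadjusted p with at least 5 CPM, skipping predicted and pseudogene symbols, given as values only. It added up to 4 members per list past the threshold, or else the 2 with the smallest p. It always took Amh, Amhr2, Gdf9, Bmp15, Zp3, Kit, Dnmt1, Ccnb1, Sod2 and Bax, and the 5 genes of highest mean CPM. Genes outside the rule are named as chosen after their values were seen, and so is a list of motile cilia genes.

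Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings and filters, the replicate number as a block, and leaving out each library in turn. For lists, the lowest and highest adjusted p over the alternatives are those of camera at the preset correlation. A covariate for cumulus markers, scaling to the oocyte-specific list, leaving out control 2 and AMH 1 together, and DESeq2 with the block were added after the data were seen.

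The tests were run on simulated counts for 18315 genes with independent genes, 192 of them changed. For AMH over control, edgeR recovered 3.1% of 65 genes changed 2-fold, 54.7% of 64 changed 4-fold and 79.4% of 63 changed 8-fold. Unchanged genes made up 11.2% of its 98 calls and 43.5% of the 216 calls of DESeq2. Such shares depend on how many genes change, so they do not give the share of false calls in the real libraries. Summaries and figures used Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9.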

Results

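Polyadenylated RNA of mouse oocytes was measured in 3 control libraries and 3 libraries of mice given AMH (anti-Müllerian hormone), a hormone of granulosa cells. Count totals were 72109080, 71804729 and 69997949 in controls 1, 2 and 3 and 69395450, 66569227 and 66392859 in AMH 1, 2 and 3. The most abundant transcripts were those of Zbed3, Gdf9, Plat, H1foo and Spin1. Zbed3 (13, 95323612 to 95337841) had 19840 ± 3665 CPM in control and 12691 ± 2006 CPM in AMH libraries (SD, n = 3 each). The title of the series asks how AMH treatment bears on oocyte quality, and the comparison made here is AMH against control.

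Between AMH and control oocytes, among protein-coding genes with a mean of at least 5 CPM, the 10 of smallest p were mostly ribosomal and respiratory chain genes, with higher values in AMH libraries. Rps13, a small ribosomal subunit protein (7, 116331505 to 116334195), had 9.19 ± 1.85 CPM in control and 32.7 ± 6.12 CPM in AMH libraries (SD, n = 3 each). Rplp1 had 17.4 ± 2.32 against 46.2 ± 6.22 CPM, and Uqcr11, a complex III subunit, had 18.8 ± 5.32 against 51.2 ± 4.85 CPM. Dynll1, a dynein light chain, had 32.6 ± 4.88 against 87.9 ± 14.1 CPM. Slpi, a secreted protease inhibitor, had 0.252 ± 0.163 against 10.3 ± 7.40 CPM. The other 5 of the 10 genes were Rps27a, Rpl31, Rps29, Naa38 and Uqcrq, each with every AMH library above every control. Genes of lower CPM had smaller p, among them Cfap100 and Stoml3, named after their values were seen. Cfap100 had 0.0463 ± 0.0157 against 1.01 ± 0.185 CPM, and Stoml3 had 0.0515 ± 0.00944 against 0.805 ± 0.0580 CPM.

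None of these genes passed the test: edgeR's quasi-likelihood test called 0 of 18868 genes, with a lowest adjusted p of 0.116. At an unadjusted p under 0.05 edgeR had 3814 genes higher and 3266 lower in AMH libraries. DESeq2 called 3067 higher and 1468 lower, limma-voom called 0, limma-voom with sample quality weights called 7357 higher and 6744 lower, and limma on FPKM called 0. The weights in that fit ran from 0.250 for AMH 3 and 0.308 for control 3 to 6.58 for control 1. Without control 3 edgeR called 5291 genes higher and 2222 lower, without AMH 3 it called 285 higher and 1322 lower, and without any 1 of the other libraries it called 0. DESeq2 called 9686 genes without control 3, 7169 without AMH 3, 1456 without control 2, 506 without control 1, 279 without AMH 2 and 267 without AMH 1. With an absolute log2 fold change of at least 1, edgeR called 0 genes and DESeq2 called 2669 higher and 206 lower.

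**Figure D1:**
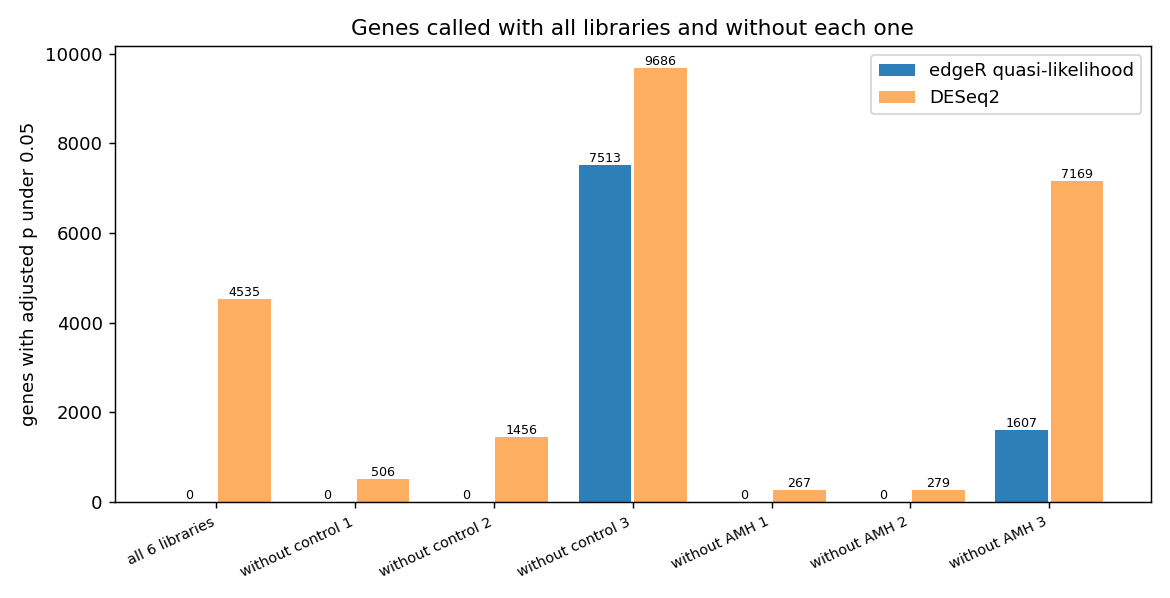
Bars give the number of genes with adjusted p under 0.05 (vertical axis) by edgeR's quasi-likelihood test (blue) and DESeq2 (orange), with all 6 libraries and without each one in turn (horizontal axis). edgeR called 0 genes with all libraries, 7513 without control 3 and 1607 without AMH 3.

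The split of genes at an unadjusted p under 0.05 moved with the scaling. It was 5256 higher and 1237 lower with library size only, 3392 higher and 4854 lower with upper-quartile scaling, and 7355 higher and 21 lower with scaling to the oocyte-specific list, a setting chosen after seeing the data. The median log2 fold change of all tested genes was -0.01 with TMM, 0.26 with library size only, -0.23 with upper-quartile scaling and 0.74 with oocyte-list scaling. Directions below are therefore relative to TMM.

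Transcripts typical of oocytes had lower mean values in AMH libraries, mostly through AMH 1 and 2. Summed CPM of the oocyte-specific list was 50450, 52001 and 42960 in controls 1, 2 and 3. It was 25704, 24696 and 42416 in AMH 1, 2 and 3, so AMH 3 lay close to control 3. Of 31 tested oocyte-specific genes all had a negative log2 fold change, with a median of -0.71, and 20 lay in every AMH library below every control, as did 23.3% of all tested genes (chance gives 10% over both directions). Bmp15, an oocyte growth factor (X, 6314107 to 6320721), had 2154 ± 282 CPM in control and 1294 ± 373 CPM in AMH libraries (SD, n = 3 each), and Gdf9 (11, 53431023 to 53437904) had 11087 ± 956 against 7061 ± 2706 CPM. The groups overlapped for Gdf9, with 10185 CPM in AMH 3 and 10041 CPM in control 3. Zp3, a zona pellucida protein, had 220 ± 133 against 93.0 ± 22.4 CPM, and Kit, the receptor of Kit ligand, had 572 ± 53.7 against 346 ± 97.0 CPM. Dazl had 774 ± 108 against 479 ± 59.1 CPM, and Figla had 2.51 ± 0.988 against 0.985 ± 0.143 CPM. Over all genes tested 0 members passed edgeR's test, and 0 when adjusted over the list alone. The list was lower by camera at the preset correlation (adjusted p = 4.88e-07, adjusted p = 0.509 with an estimated correlation), and its median was -0.01 with oocyte-list scaling by construction. Summed cumulus marker CPM in the same libraries was 4598 ± 2874 in control and 8550 ± 1036 in AMH libraries, and with it as a covariate, a setting chosen after seeing the data, the list median was -0.33.

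Maternal-effect genes, whose products the early embryo uses, had a median of -0.78 with TMM and -0.04 with oocyte-list scaling over 27 members, with 0 past the test over all genes and 16 lower when adjusted over the list alone. Nlrp14 had 899 ± 297 CPM in control and 431 ± 6.45 CPM in AMH libraries, and Cdh1 had 843 ± 82.5 against 506 ± 96.4 CPM (SD, n = 3 each). The list was lower by camera (adjusted p = 6.08e-06, adjusted p = 0.509 with an estimated correlation). Its summed CPM was 42375, 44482 and 32848 in controls 1, 2 and 3, and 21183, 23228 and 29813 in AMH 1, 2 and 3. AMH 3 thus lay below every control, though close to control 3. Genes of mRNA storage and decay had a median of -0.63 with TMM and 0.09 with oocyte-list scaling, and adjusted over the list alone 19 members were lower and 2 higher. Cpeb1, which controls polyadenylation of stored mRNA (7, 81347026 to 81455465), had 414 ± 64.0 against 221 ± 24.8 CPM, and Cpeb4 had 50.4 ± 1.51 against 30.03 ± 3.88 CPM. That list was lower by camera (adjusted p = 0.000152, adjusted p = 0.509 with an estimated correlation). With the cumulus covariate the medians of these lists were -0.29 and -0.26.

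Genes of meiosis and chromosomes lay lower as well, again mostly in AMH 1 and 2. Summed spindle and cohesion CPM was 7018 and 8086.5 in AMH 1 and 2 and 10945 in AMH 3, against 14060, 14955 and 12138 in controls 1, 2 and 3. The spindle and cohesion list had a median of -0.64 with TMM and 0.11 with oocyte-list scaling (camera adjusted p = 6.08e-06, adjusted p = 0.509 with an estimated correlation), and Kif18a, a mitotic kinesin, had 127 ± 12.1 against 79.2 ± 13.6 CPM. Rec8, a meiotic cohesin subunit in the same list, went the other way at very low values, with 0.00506 ± 0.00876 against 0.467 ± 0.373 CPM and every AMH library above every control. The meiotic cell-cycle list had a median of -0.51 with TMM and 0.19 with oocyte-list scaling (camera adjusted p = 0.00407, adjusted p = 0.509 with an estimated correlation). In it Mastl had 302 ± 42.0 against 168 ± 29.7 CPM, and Ccnb1, the cyclin of maturation promoting factor, had 2748 ± 140 against 1763 ± 529 CPM. DNA repair genes had a median of -0.38 with TMM (camera adjusted p = 0.00383, adjusted p = 0.509 with an estimated correlation) and 0.36 with oocyte-list scaling, where the call was lost (adjusted p = 0.0925, range over the alternatives 0.00177 to 0.0925). In that list Fancm had 82.4 ± 9.46 against 46.2 ± 8.78 CPM. Chromatin modifiers had a median of -0.36 with TMM and 0.36 with oocyte-list scaling (camera adjusted p = 0.0450, adjusted p = 0.516 with an estimated correlation), a call lost in 7 of 13 alternatives at the preset correlation, whose adjusted p ran from 0.0138 to 0.386. The call was lost at a similar median without control 3 (-0.32, adjusted p = 0.0649) and with at least 5 CPM in 3 libraries (-0.32, 0.111). It was lost at a smaller one without AMH 1 (-0.21, 0.0957), without control 2 and AMH 1 (-0.18, 0.0762), with library size only (-0.09, 0.0937) and with the cumulus covariate (-0.17, 0.0933), and with oocyte-list scaling (0.36, 0.386). Without AMH 3 the median was -0.54. Dnmt1, the maintenance DNA methyltransferase, had 737 ± 164 against 429 ± 132 CPM, while Hdac1 had 23.9 ± 8.86 against 53.4 ± 5.84 CPM. With the cumulus covariate the medians of these 4 lists were -0.30, -0.26, -0.21 and -0.17. Over all genes tested and adjusted over each list alone, 0 members passed.

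Transcripts of ribosomal proteins and of the respiratory chain had higher values in AMH libraries. Of 82 cytosolic ribosomal protein genes, 74 lay in every AMH library above every control, where chance gives 5% in that direction and 26.9% of all tested genes did so, and the median log2 fold change was 1.64. For 79 nuclear oxidative phosphorylation genes the median was 1.35, and for 77 mitochondrial ribosomal protein genes 0.88. Mrpl11 had 4.47 ± 0.977 CPM in control and 13.2 ± 2.66 CPM in AMH libraries, and Uqcrq had 16.4 ± 3.99 against 46.2 ± 8.23 CPM (SD, n = 3 each). Over all genes tested 0 members passed edgeR's test. Adjusted over the list alone 73 cytosolic ribosomal genes were higher, 66 oxidative phosphorylation genes were higher and 1 lower, and 43 mitochondrial ribosomal genes were higher and 1 lower. Camera called all 3 lists higher (adjusted p = 8.38e-17, 3.65e-15 and 2.45e-06), with adjusted p = 0.509 for each with an estimated correlation. Mean cumulus marker CPM, at 4598 in control and 8550 in AMH libraries, moved the same way as these lists, but single libraries did not all follow it. Control 3 had 7838 and AMH 3 had 7407 cumulus marker CPM. Summed cytosolic ribosomal CPM was 2378 in control 3 and 4010 in AMH 3, and oxidative phosphorylation CPM 4200 and 5313. With cumulus marker CPM as a covariate the medians of the 3 lists were 0.97, 0.75 and 0.50.

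**Figure D2:**
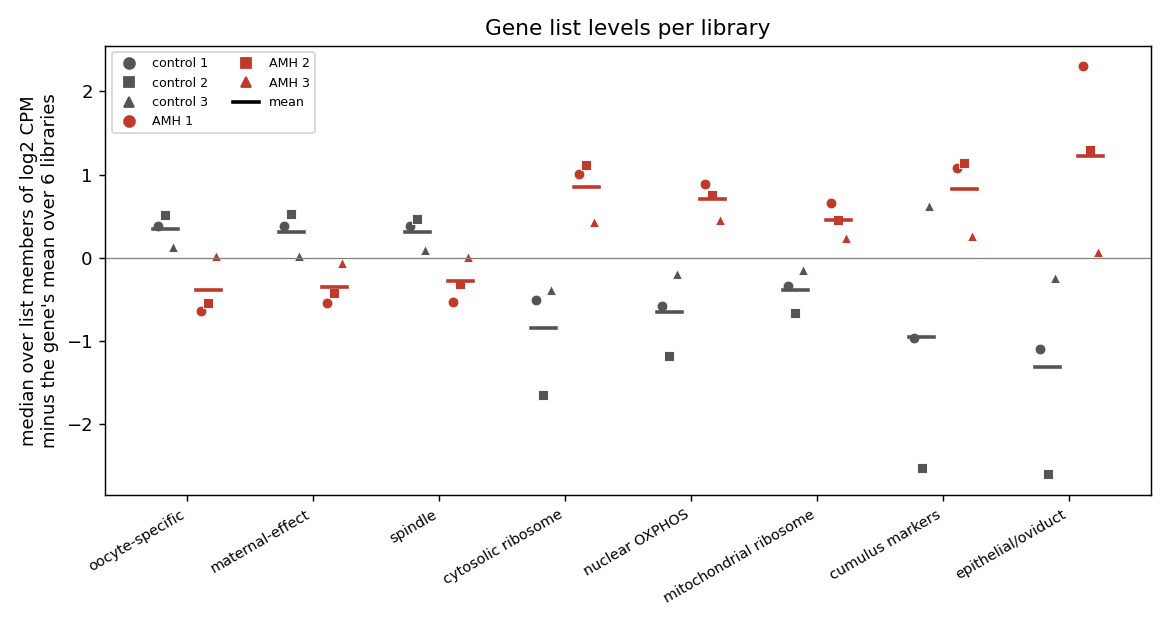
Each point is 1 library (grey control, red AMH, symbol by replicate number) and each bar a group mean. The vertical axis is the median over list members of log2 CPM minus the gene's mean over the 6 libraries, and cytosolic ribosomal genes sit between -1.64 and -0.39 in controls and between 0.43 and 1.12 in AMH libraries.

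Mitochondrially encoded mRNAs had a median of 0.61 over 12 genes, and mt-Co1, a complex IV subunit (MT, 5328 to 6872), had 216 ± 39.8 against 453 ± 163 CPM. Their camera call (adjusted p = 0.0299, adjusted p = 0.555 with an estimated correlation) was lost without control 3 (median 0.44, adjusted p = 0.440) or AMH 2 (median 0.31, adjusted p = 0.117), with a lowest adjusted p of 9.80e-05 over the alternatives. Antioxidant genes had a median of 1.26 over 47 members, of which 16 were higher adjusted over the list alone (camera adjusted p = 0.000106, adjusted p = 0.509 with an estimated correlation). Sod1, cytosolic superoxide dismutase, had 12.3 ± 1.66 against 27.3 ± 5.37 CPM, and Gpx3 had 202 ± 22.7 against 351 ± 62.4 CPM, while mitochondrial Sod2 had 53.0 ± 2.07 against 58.2 ± 1.47 CPM (edgeR adjusted p = 0.465). Proteasome subunits had a median of 0.60 and 15 of 48 higher adjusted over the list alone (camera adjusted p = 0.00336, adjusted p = 0.509 with an estimated correlation), with Psmb7 at 8.22 ± 2.59 against 20.4 ± 3.57 CPM. Glycolysis and tricarboxylic acid cycle genes had a median of 0.87 (camera adjusted p = 0.00316, adjusted p = 0.546 with an estimated correlation). Sdhd in that list had 36.4 ± 10.3 against 73.3 ± 17.7 CPM. Fatty acid oxidation genes had a median of 0.96 (camera adjusted p = 0.000815, adjusted p = 0.509 with an estimated correlation), and Mgll had 0.242 ± 0.0460 against 1.36 ± 0.580 CPM. Without control 3 that median was 1.66. Mean cumulus marker CPM (4598 in control and 8550 in AMH libraries) moved the same way as these lists. Among controls the mitochondrially encoded genes did not follow it: their sum was 757 CPM in control 3, which had 7838 cumulus marker CPM, against 1098 and 1033 in controls 1 and 2. With cumulus marker CPM as a covariate the medians were 0.36 for antioxidant, 0.29 for proteasome and 0.21 for fatty acid oxidation genes. The median of mitochondrially encoded genes rose from 0.61 to 0.89. The median of glycolysis and tricarboxylic acid cycle genes was 0.17 with the covariate and their call was lost (adjusted p = 0.161, range over the alternatives 0.000573 to 0.161).

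**Figure D3:**
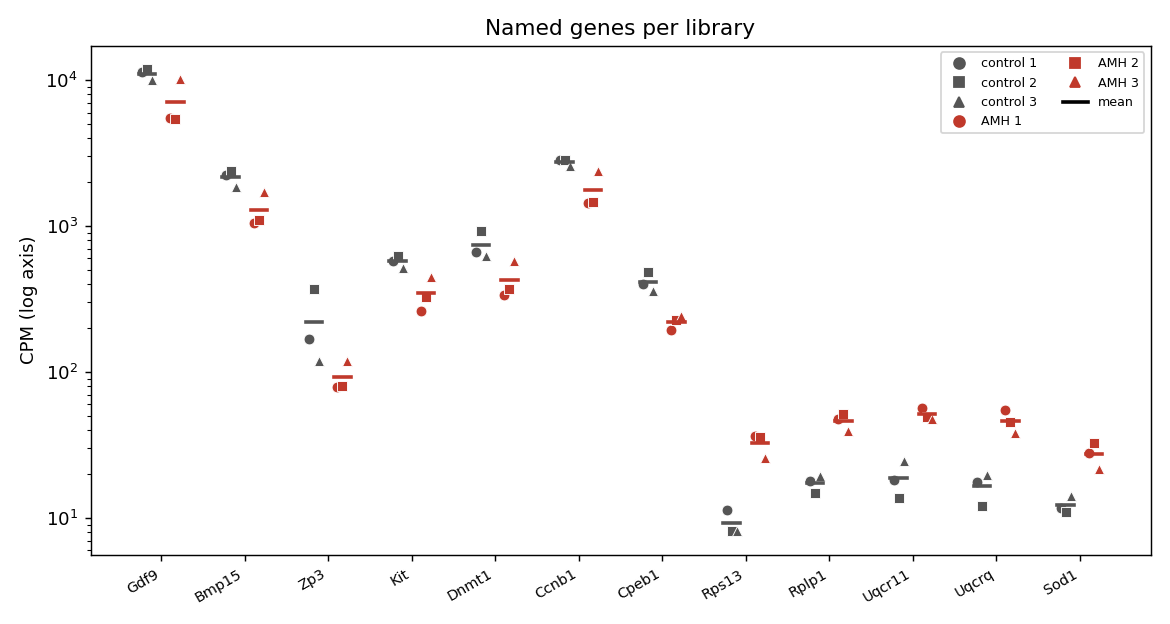
CPM (log axis) of 12 named genes per library, grey for control and red for AMH, with the group mean as a bar. Bmp15 averaged 2154 CPM in control and 1294 CPM in AMH libraries, and Rps13 averaged 9.19 and 32.7 CPM.

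The AMH and BMP/SMAD signalling list did not pass camera (median 0.40, adjusted p = 0.517), and its direction was not stable. The median was 0.04 without control 2, -0.03 without control 2 and AMH 1, and -0.21 with cumulus marker CPM (4598 in control and 8550 in AMH libraries) as a covariate. The cumulus list shares Amh, Amhr2, Inha, Inhba, Inhbb and Fst with this list, so the covariate adjusts the list partly for itself. Amhr2, the AMH receptor (15, 102445367 to 102454633), had 8.04 ± 9.51 CPM in control and 30.2 ± 4.95 CPM in AMH libraries (SD, n = 3 each, edgeR adjusted p = 0.165). In control 3 it had 18.9 CPM, against 4.30 and 0.966 CPM in controls 1 and 2. Amh itself had 1.82 ± 1.67 against 3.90 ± 1.10 CPM (edgeR adjusted p = 0.233), and Bmpr1b, a BMP receptor, had 330 ± 18.2 against 208 ± 19.5 CPM (edgeR adjusted p = 0.116). Camera also passed none of PI3K, FOXO and mTOR signalling (median 0.33, adjusted p = 0.517), apoptosis (0.49, 0.153), autophagy (0.37, 0.277), mitochondrial dynamics (0.49, 0.0673), protein folding (0.38, 0.0729) and histones (0.84, 0.0525). The PI3K median was 0.20 without AMH 1 and 0.16 without AMH 2. The mitochondrial dynamics and protein folding lists passed with library size only (medians 0.78 and 0.65, adjusted p = 0.0255 and 0.0197) and with oocyte-list scaling (medians 1.32 and 1.15, adjusted p = 0.0108 and 0.00893). Their highest adjusted p over the alternatives at the preset correlation were 0.124 and 0.383, and camera with an estimated correlation gave adjusted p = 0.509 and 0.546. The apoptosis gene Bax had 14.2 ± 5.89 against 35.9 ± 8.63 CPM, and the chaperone Hspa8 had 249 ± 116 against 751 ± 102 CPM. The histone list passed without control 1, control 2, AMH 2 or AMH 3 (adjusted p = 0.0118, 0.0328, 0.0435 and 0.0104) and with the cumulus covariate (0.000339). Its highest adjusted p at the preset correlation was 0.477, without control 3, and camera with an estimated correlation gave adjusted p = 0.509. Its median was 0.50 without control 3 and 0.50 without AMH 1. Sperm-egg interaction genes (median -0.46 with TMM and 0.31 with oocyte-list scaling) and gap junction genes (-0.33 and 0.39) did not pass either (adjusted p = 0.111 and 0.123), though the gap junction list passed as lower with the cumulus covariate (median -0.29, adjusted p = 0.0130, range over the alternatives at the preset correlation 0.0130 to 0.311). With an estimated correlation its camera adjusted p was 0.509, and it shares Gja1, Npr2 and Kitl with the cumulus list. In these lists Slc39a10 had 878 ± 57.7 against 527 ± 92.3 CPM and Jag1 had 733 ± 202 against 362 ± 24.8 CPM.

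Markers of other cell types differed in level between libraries, along with the oocyte and ribosomal lists. Summed cumulus and granulosa marker CPM was 3600, 2357 and 7838 in controls 1, 2 and 3 and 9427, 8815 and 7407 in AMH 1, 2 and 3, so control 3 lay within the AMH range. The group means were 4598 ± 2874 and 8550 ± 1036 CPM (SD, n = 3 each; two-sided exact permutation p = 0.2, adjusted 0.233 over 7 lists), and the control mean was 2978 CPM without control 3. Inhba, an inhibin and activin subunit, had 39.8 ± 38.0 against 170 ± 26.3 CPM. Epithelial and oviduct markers summed to 114 ± 84.6 against 475 ± 304 CPM (exact permutation p = 0.2), with 8 of 14 members higher adjusted over the list alone. Their control mean was 67.2 CPM without control 3, and their AMH mean 315 CPM without AMH 1. Foxj1, a regulator of motile cilia, had 0.144 ± 0.0725 against 3.00 ± 2.23 CPM, and Krt7 had 0.241 ± 0.141 against 5.14 ± 4.86 CPM. Blood and immune markers summed to 38.1 ± 19.7 against 256 ± 182 CPM (exact permutation p = 0.1, the smallest possible), and the AMH mean was 152 CPM without AMH 1. Hba-a1, an alpha globin, averaged 0.695 ± 0.926 against 69.6 ± 97.8 CPM. It had 183 CPM in AMH 1 against 14.9 and 11.3 CPM in AMH 2 and 3. In control 3 it had 1.76 CPM, against 0.248 and 0.0779 CPM in controls 1 and 2. The exact permutation p was also 0.1 (adjusted 0.175 over 7 lists) for summed theca, endothelial and two-cell embryo markers. Theca markers summed to 459 ± 243.6 against 1078 ± 250 CPM. Endothelial markers summed to 259 ± 23.95 against 169.5 ± 41.6 CPM, and two-cell embryo markers to 440 ± 25.3 against 301 ± 54.35 CPM, both lower in AMH libraries.

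Camera called the cumulus (median 1.34, adjusted p = 0.000471, adjusted p = 0.546 with an estimated correlation), blood (2.15, adjusted p = 0.000301, adjusted p = 0.509 with an estimated correlation) and epithelial lists (2.69, adjusted p = 0.00381, adjusted p = 0.509 with an estimated correlation) higher. Without control 3 the cumulus median was 2.67 and the blood median 3.56, and without control 2 the cumulus median was 0.84. With the cumulus covariate the camera direction of the cumulus and theca lists turned (medians 0.11 and 0.12). The cumulus list is itself the source of that covariate, so its own turn carries no information. The epithelial call was lost with at least 5 CPM in 3 libraries (median 1.69, adjusted p = 0.246) and, at a larger median, with oocyte-list scaling (3.46, 0.0651), with a lowest adjusted p of 0.00197 over the alternatives. Immediate-early genes were called higher too (median 1.59, adjusted p = 0.00407, adjusted p = 0.555 with an estimated correlation). Their summed CPM was 3537 and 3842 in AMH 1 and 2 and 1156 in AMH 3, against 758 to 1592 in controls, and Klf2 had 18.6 ± 6.69 against 50.9 ± 12.4 CPM. Their call was lost with the cumulus covariate (median 0.48, adjusted p = 0.198), without control 2 and AMH 1 (1.02, 0.120) and, at a larger median, with oocyte-list scaling (2.38, 0.186), with a lowest adjusted p of 4.15e-05 over the alternatives. The two-cell embryo list was lower (median -0.73 with TMM and 0.04 with oocyte-list scaling, adjusted p = 0.0291, adjusted p = 0.509 with an estimated correlation), with Nelfa at 382 ± 22.0 against 247 ± 58.0 CPM, a call lost with the cumulus covariate (median -0.29, adjusted p = 0.148, range over the alternatives 0.00115 to 0.148). Theca and stromal markers (median 1.39, adjusted p = 0.0906, adjusted p = 0.585 with an estimated correlation) passed without control 3 (median 2.57, adjusted p = 0.0222) and with at least 5 CPM in 3 libraries (1.81, 0.0398), with a highest adjusted p of 0.824 over the alternatives. Without AMH 1 their median was 0.68. Endothelial markers did not pass (adjusted p = 0.602), with a median of -0.33 with TMM, 0.38 with oocyte-list scaling and a mean of 0.49, and passed as lower with at least 5 CPM in 3 libraries (median -0.60, adjusted p = 0.0162, range over the alternatives 0.0162 to 0.951). Their median was -0.04 without AMH 1, -0.21 without control 1 and -0.51 without AMH 3. Flt1 in that list had 28.2 ± 2.90 against 13.7 ± 1.04 CPM, and Esam had 0.0662 ± 0.0683 against 0.737 ± 0.429 CPM.

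**Figure D4:**
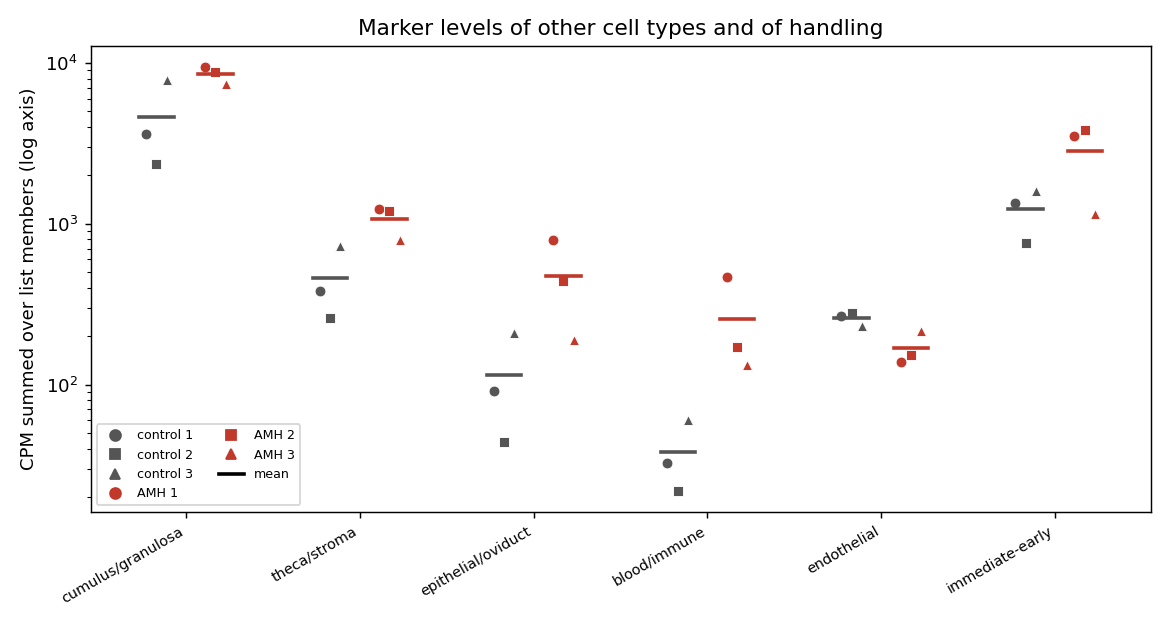
Summed CPM (log axis) of 6 marker lists per library, grey for control and red for AMH, with the group mean as a bar. Cumulus markers were 7838 CPM in control 3 and 7407 CPM in AMH 3.

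AMH libraries held more detected genes. Genes with at least 10 counts numbered 17964 ± 347 in control and 19261 ± 369 in AMH libraries (SD, n = 3 each), and 17785 ± 381 against 19222 ± 326 after thinning to 66392859 counts. The 100 most counted genes took 25.1 ± 1.42% of counts in control and 20.7 ± 2.15% in AMH libraries, and mitochondrial genes took 0.105 ± 0.0216% and 0.202 ± 0.0756%. For each of these measures the two-sided exact permutation p was 0.1, the smallest possible, or 0.171 after adjustment over 12 measures. The first principal component held 76.6% of the variance, with control 2 at -174.5, control 1 at -79.7, control 3 at 14.3, AMH 3 at 47.9, AMH 2 at 86.3 and AMH 1 at 105.6. In that order of libraries, centred log2 cumulus marker CPM was -1.317, -0.706, 0.417, 0.335, 0.586 and 0.683. The component thus ran with cumulus marker level as well as with group, and cannot be read as an axis of AMH alone. Control 3 correlated with the AMH libraries at 0.955 to 0.978 across genes, and with the other controls at 0.919 and 0.962. Control 3 and AMH 3, at 0.978, were each other's closest match.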

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

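The cumulus covariate, oocyte-list scaling, the joint omission of control 2 and AMH 1, DESeq2 with the block, and the left-out libraries for DESeq2 and for unadjusted p were chosen after the data were seen. The count of 0 genes by edgeR held under limma-voom, RLE, upper-quartile and library-size scaling, 3 other gene filters, the 3 added edgeR settings and limma on FPKM. DESeq2 gave 4535 genes, 2875 of at least 2-fold and 464 list members, and limma-voom with quality weights gave 14101 and 7421. Leaving out 1 library gave 0 to 7513 genes, 0 to 5649 of at least 2-fold, 0 to 6882 from FPKM, 267 to 9686 by DESeq2 against 4535, and 2816 to 10571 with unadjusted p under 0.05 against 7080. FPKM with a pseudocount of 5 gave 3079 genes. Unadjusted counts were 14511 with quality weights, 1144 with the covariate and 1916 without control 2 and AMH 1. Camera called 20 lists, and 0 with an estimated correlation and 0 by fry. Detected genes differed by 1297 at 10 counts and by 1930 at 1 count. For all of these the cause was not tested.

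With the replicate number as a block edgeR gave 0 genes and 4671 with unadjusted p under 0.05, and FPKM gave 0 genes. DESeq2 with the block gave 3486 genes higher and 122 lower, against 3067 and 1468 without it. Camera gave 21 lists with the block, the added one being histones (median 0.86, adjusted p = 0.0387). Deviations of libraries with equal numbers correlated at 0.06, -0.10 and -0.25, and in these deviations from the group means no library correlated best with its own number, so the numbers were not taken to pair libraries.

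List medians whose camera direction turned were, with the covariate, AMH and BMP/SMAD signalling -0.21, autophagy 0.061, cumulus 0.11 and theca 0.12, and without control 2 and AMH 1 AMH and BMP/SMAD signalling -0.03. The covariate is built from the cumulus list, which is thus adjusted wholly for itself. The AMH and BMP/SMAD list shares genes with it and is adjusted partly for itself. The theca list shares only Lum with the cumulus list, and the autophagy list shares no gene with it. With oocyte-list scaling, log2 fold changes turned for Dazl 0.049, Kif18a 0.050, Bmpr1b 0.077, Ski 0.003, Wrn 0.093, Smarca5 0.013, Atp2b1 0.116, Atg5 0.122, Nelfa 0.077, Ccnb1 0.051, Gdf9 0.027, Zbed3 0.096, Plat 0.071, H1foo 0.037 and Spin1 0.017, a scaling built to bring oocyte genes to 0. In simulated data of this depth and spread edgeR recovered 3.1% of 65 genes changed 2-fold and 79.4% of 63 changed 8-fold. Genes were independent there, while 1 component held 76.6% of the variance of the real libraries, so these shares do not measure what could be detected here. Slpi, 40.5-fold higher with every AMH library above every control, had an edgeR adjusted p of 0.116. Large changes could thus be missed as well as small ones.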

Other observations

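All tests of explanations below, except the counts over other splits of the libraries, were chosen after the result was seen. Some motile cilia genes, such as Tekt1 (edgeR unadjusted p = 0.000725), had small p. The oviduct gene Ovgp1 ranked further down (edgeR unadjusted p = 0.0113). The genes named here were chosen after their values were seen. Ovgp1, the oviduct glycoprotein, had 16.6, 2.52 and 21.7 CPM in controls 1, 2 and 3 and 379, 164 and 31.8 CPM in AMH 1, 2 and 3. Tekt1, a ciliary tektin, had 0.140, 0.140 and 0.182 CPM against 3.88, 1.2 and 1.04 CPM, and the complement gene C3 had 1.44, 0.561 and 2.09 CPM against 35.0, 11.3 and 10.4 CPM. Globin transcripts were highest in AMH 1, with Hbb-bs at 113 CPM against 9.66 and 7.72 CPM in AMH 2 and 3. Egr1 had 411 and 461 CPM in AMH 1 and 2 but 65.5 CPM in AMH 3, against 56.1 to 140 CPM in controls.

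A candidate source of the ciliary and oviduct transcripts is oviduct epithelium carried with the oocytes. Summed CPM of the 14 epithelial and oviduct markers lay above every control in 2 of the 3 AMH libraries, while AMH 3 had 189.5 against 208 CPM in control 3. Krt8 and Krt18 made up most of the sum there, at 59.6 and 39.6 CPM in AMH 3 and 80.0 and 64.0 CPM in control 3. The sum thus says little of the other members. Of the 14, 8 lay in every AMH library above every control and 1 below, where 26.9% of all tested genes lay above. This source stays open, as does an effect of AMH, which was not tested. The motile cilia list was chosen after its members' values were seen and tests nothing: 15 of 24 genes lay in every AMH library above every control (chance gives 5%, and 26.9% of all tested genes lay so), and 3 (Ccno, Dnah9 and Drc1) below every control. Summed CPM of the 24 genes was 449.8, 589.7 and 356.9 in controls against 368.7, 322.8 and 375.7 in AMH libraries. Most of that sum came from Ccno, Tubb4b and Dnah9 (194, 153 and 61.7 CPM in control 1), so it does not follow the other members. The control libraries already held 6 of the 24 and 5 of the 14 at 5 CPM or more. Carry-over with the cumulus cells at a fixed ratio cannot be told apart from a separate source: the ratio of summed epithelial to summed cumulus CPM was 0.0837 and 0.0498 in AMH 1 and 2, above the controls' 0.0185 to 0.0265, but 0.0255 in AMH 3, and the mean log2 ratio was 1.03 higher in AMH libraries, within the summed SDs of 1.14. The ratio of AMH 3 rests on the same sum, mostly Krt8 and Krt18.

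Higher ribosomal and lower oocyte transcripts may reflect more cumulus RNA beside each oocyte in AMH libraries, where the labels do not say whether cumulus cells were removed. With the cumulus marker level as a covariate the difference of the ribosomal list mean went from 1.55 to 0.95 (95% interval -0.38 to 2.28) and that of the oocyte list from -0.75 to -0.32 (-1.06 to 0.41). Both intervals hold 0 and the unadjusted value, so cumulus RNA and AMH cannot be told apart with 6 libraries. Control 3 had more cumulus marker CPM than AMH 3 (7838 against 7407) but less summed ribosomal CPM (2378 against 4010). Their oocyte-list sums were alike (42960 and 42416 CPM). In controls 1, 2 and 3 ribosomal CPM was 2162, 1194 and 2378, beside cumulus marker CPM of 3600, 2357 and 7838. Ribosomal CPM kept the order of the cumulus markers there but rose little from control 1 to control 3. Comparisons of single libraries do not decide between cumulus RNA and AMH. Gene length as the whole cause is argued against: lists matched on length and expression had a median log2 fold change of 0.23 (95% range -0.03 to 0.53), against 1.5 for the 161 ribosomal and respiratory genes. For the oocyte list they had -0.36 (-0.54 to 0.18), against -0.71, so part of that fall is shared by genes of like length and expression. The matched lists were random, while the ribosomal, respiratory and oocyte lists co-vary (estimated correlations 0.63, 0.53 and 0.65). The ranges are thus narrower than co-varying lists would give, which weakens the argument most for the oocyte list.

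Control 3 lay closer to the AMH libraries than the other controls did, and closest to AMH 3. Its cumulus marker level was 1.12 log2 units above the higher of the other controls and inside the AMH range, which is consistent with more cumulus RNA in that library. A wrong label cannot be told apart from this with 1 library. Of 120 oviduct, cilia and ribosomal genes, control 3 lay above both other controls and inside the AMH range in 4, and below all 3 AMH libraries in 106. That tally decides nothing, since the cilia genes were chosen after their values were seen. Genes with every AMH library above every control, such as 74 of the 82 ribosomal genes, also place control 3 below by construction. No biological explanation of its position was tested.

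The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. All 10 splits gave at least the 0 genes of edgeR, where the highest other split had 0, and all 10 gave at least the 0 genes of limma on FPKM, where the highest other had 0. The real split had 7080 genes at an unadjusted p under 0.05 against 1995 in the highest other, and 4535 by DESeq2 against 106, and 1 of the 10 splits, the real one, reached each count. Camera called 20 lists in the real split, and 2 of the 10 splits gave as many. The other was controls 1 and 2 with AMH 3 against control 3 with AMH 1 and 2, which also calls 20 lists.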
